A study of Mus musculus with 11 samples.

How the data were processed

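Small RNA was sequenced from sorted mouse splenic CD8+ T cells. Per the labels' protocols, CD8+ cells were enriched with CD8a microbeads, and CD4- CD8+ CD49dlo GFP+ cells were sorted by CD44 into a CD44hi fraction, named stamped VM, and a CD44lo fraction, named stamped TN. Virtual memory (VM) cells are CD8+ T cells with a memory phenotype that have not met foreign antigen, and TN cells are true naive cells. Post-sort purity was over 95% per the labels' protocols, and 10000 sorted cells went into Trizol. Libraries were made with the NEBNext Small RNA kit from 60 to 100 ng of total RNA, with inserts of about 18 to 35 bp.

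The deposited table held 2128 rows, one per mature miRNA and precursor hairpin, and 11 columns, one per library. Its values were expected counts, that is, estimated counts as the authors deposited them, with 88.7% of the values whole (equal to their rounded value) and 386 rows holding at least 1 fractional value. Zeros count as whole in that share, and only 1268 rows had a count in any library. The submitters' processing notes name the genome build mm10. The aligner, the counting program and the annotation release were not given in the sources used here. No scaling between libraries was found in the values, whose totals differed by up to 6.24-fold.

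The 2128 rows carried 1978 mature names, of which 85 stood on more than 1 row, since 1 mature sequence can come from several hairpins. Rows with an identical name and identical values in all 11 libraries were kept once, which removed 120 rows that held 0.89% of all counts and left 2008. Estimated counts were rounded to whole numbers before fitting. No row named anything other than a miRNA. Rows of the same miRNA from different hairpins stayed separate, with the hairpin in brackets, and an alternative summed them.

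Libraries formed 4 groups by the titles: Clean_TN with 2 libraries (replicates 2 and 3), and Clean_VM, Dirty_TN and Dirty_VM with 3 each. The table held no column for a replicate 1 of Clean_TN. Rows were filtered with filterByExpr on the 4 groups, which kept 545 rows of 524 distinct miRNAs and 99.99% of the counts. One quasi-likelihood model was fitted over all 11 libraries in edgeR 4.0.16 (estimateDisp, then glmQLFit with robust estimation) with TMM scaling and 1 mean per group. Contrasts compared VM with TN cells in clean mice, in dirty mice and averaged over both, and dirty with clean mice in TN cells, in VM cells and averaged over both. A further contrast, the interaction, tested whether the VM minus TN difference itself differed between dirty and clean mice. All tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the 545 rows with a threshold of 0.05. Levels are counts-per-million (CPM) values on TMM-scaled totals, given as the group mean ± SD over libraries. Fold changes are log2 estimates ± a standard error (SE) worked back from the test. It is the absolute log2 change divided by the square root of the quasi-likelihood F statistic.

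The named miRNAs followed a rule. Within each contrast it took miRNAs with an adjusted p under 0.05, a mean level of 10 CPM or more over the libraries compared, and no overlap between the libraries of the groups compared, within each environment or subset for the averaged contrasts. Of these, the 10 largest increases and the 10 largest decreases were named. Where no miRNA passed, the 5 with the smallest p-values, or the 3 for the interaction, were named as not passing. Tested members of the fixed lists that passed, some that did not, and the most abundant miRNAs were named as well. The contrasts, the tests, this rule, the miRNA lists and most alternatives were fixed before the data were examined.

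The fixed lists covered 13 T cell or miRNA family groups: the let-7 family, the miR-17-92 cluster and paralogs, the miR-15/16, miR-181, miR-29, miR-30, miR-130/301 and miR-148/152 families, the miR-23/27/24 clusters, the miR-99/125 group, T cell activation and memory miRNAs, resting T cell miRNAs and the imprinted Dlk1-Dio3 cluster. Another 6 lists held miRNAs of other cells that a spleen sort could carry: erythroid, myeloid, endothelial and platelet, stromal, epithelial, and hepatocyte and muscle miRNAs. Of the 19 lists, 16 had 3 or more tested members and were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with p-values adjusted over the lists of a contrast. A miRNA on several rows entered its list as its most abundant row.

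Alternatives replaced 1 choice at a time. They were DESeq2 1.42.0, limma-voom, DESeq2 size factors in edgeR, library totals without further scaling, no filter beyond 1 count, a stricter filter of 10 CPM in at least 2 libraries, rows summed per miRNA, the replicate number as a block, and a block per environment and replicate number. Further alternatives fitted only the libraries of the groups compared, or left out each library in turn. For lists they were camera with an estimated correlation and fry. After the totals were seen, the libraries were put into a shallow class (5 libraries under 5 M counts) and a deep class (6 libraries), and this depth class was added as a term or used to fit the classes apart.

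Shares of the counts held by the most abundant miRNAs of each library were compared by two-sided exact permutation tests in scipy 1.17.1. Genome positions came from the GENCODE M21 annotation of mm10, matched by the precursor name among the RefSeq synonyms or by the gene symbol, and 400 of the 407 tested precursors were placed. A host gene is a gene of another type on the same strand that spans the hairpin. The pipeline was tested on simulated data with the same groups and depths and 545 rows. Depending on the contrast, 186 to 194 of the tested rows carried a true log2 change of 1 or 2, up or down. The simulated spread followed the trend over level, with none particular to a row or library. Where few rows truly change, the adjusted threshold is harder to reach. The shares called are therefore no estimate for contrasts with few changes. A true log2 change of 1 was called for 30.1% of changed rows in the clean contrast and 71% in the averaged VM against TN contrast, and a log2 change of 2 for 77.9% and 94.6%. For dirty against clean, a log2 change of 1 was called for 34% of changed rows in TN cells and 37.5% in VM cells. Between 0.9% and 7.2% of the simulated calls were false, depending on the contrast. Other software was R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.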

Results

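Mature miRNAs were counted by small RNA sequencing in 11 libraries of splenic CD8+ T cells from mice labelled clean or dirty. Each environment had stamped true naive (TN, CD44lo) and stamped virtual memory (VM, CD44hi) cells, and the labels define neither dirty nor stamped. There were 2 Clean_TN libraries (replicates 2 and 3), 3 Clean_VM, 3 Dirty_TN and 3 Dirty_VM. Nothing says that the replicates came from separate animals, so every p-value here measures the spread between these libraries. Total estimated counts were 9835364 and 3118537 for Clean_TN replicates 2 and 3. They were 4116012, 10630453 and 10492633 for Clean_VM replicates 1, 2 and 3, and 9399645, 3621364 and 10945831 for Dirty_TN. For Dirty_VM they were 3093915, 2614396 and 16312004. Between 645 and 846 miRNAs had a count per library. A count of 0 allowed a level of up to 0.186 to 1.157 CPM, taking 3 counts as the floor, and such floors cover counting error only.

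A few miRNAs made up most of each library. let-7f-5p held 22.09% of the counts as the mean of the 4 group means, let-7g-5p 15.26%, miR-150-5p 10.21%, let-7a-5p 7.27% and miR-92a-3p 6.8%. miR-150-5p, which is abundant in mature lymphocytes and represses Myb, held 14.26% ± 0.05 (SD, n = 2) in Clean_TN, 8.17% ± 1.61 (n = 3) in Clean_VM, 9.57% ± 4.63 (n = 3) in Dirty_TN and 8.82% ± 1.28 (n = 3) in Dirty_VM. let-7f-5p held 18.72% ± 1.17 in Clean_TN and 26.48% ± 0.22 in Clean_VM, against 24.82% ± 5.25 in Dirty_TN and 18.35% ± 1.55 in Dirty_VM. The 10 most abundant miRNAs of each library, not a fixed set, held 75.84% ± 1.32 (SD, n = 6) of the counts in VM and 76.95% ± 1.55 (n = 5) in TN libraries. The difference was -1.12 points (two-sided exact permutation test, p = 0.242, adjusted p = 0.484). Within the shallow libraries (5 libraries with totals up to 4116012) this difference was -1.41 points and within the deep ones -0.84. In the 10 most abundant of each library, dirty libraries held 76.05% ± 1.96 (n = 6) and clean libraries 76.7% ± 0.56 (n = 5). That difference was -0.65 points (two-sided exact permutation test, p = 0.506, adjusted p = 0.506), with -0.73 in the shallow and -0.52 in the deep libraries.

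The comparison of VM with TN cells, averaged over clean and dirty mice, asked which miRNAs differ between the subsets on average over the environments. VM cells had more miR-21a-5p, which is induced on T cell activation, with a log2 change of 1.88 ± 0.13 (SE, adjusted p = 6.5e-07, edgeR quasi-likelihood). Its level was 9360 ± 1220 CPM (SD, n = 2) in Clean_TN, 30100 ± 3230 (n = 3) in Clean_VM, 12900 ± 1640 (n = 3) in Dirty_TN and 54400 ± 5000 (n = 3) in Dirty_VM. Both arms of the hairpin in the Pde2a intron rose, miR-139-5p by 1.74 ± 0.13 (adjusted p = 6.5e-07) and miR-139-3p by 2.18 ± 0.27 (adjusted p = 5.2e-05). miR-181a-5p, which sets T cell receptor sensitivity in thymocytes, fell by 1.69 ± 0.15 on the log2 scale (adjusted p = 4.7e-06). miR-211-5p, a melanocyte miRNA encoded in a Trpm1 intron, fell by 2.19 ± 0.16 (adjusted p = 6.5e-07).

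In this averaged comparison 129 of the 545 rows passed, 62 higher and 67 lower in VM cells. The largest increases among the named miRNAs included miR-30c-2-3p and miR-30a-3p, with log2 changes of 2.77 ± 0.24 and 2.25 ± 0.17. miR-504-5p rose by 1.63 ± 0.16, miR-130b-5p by 1.62 ± 0.26, miR-30a-5p by 1.52 ± 0.27, miR-31-5p by 1.45 ± 0.35 and miR-10a-5p by 1.22 ± 0.14. Among the decreases, miR-181a-2-3p fell by 2.7 ± 0.31, miR-125a-5p by 2.07 ± 0.2 and miR-99b-5p by 1.62 ± 0.19. miR-3964 fell by 1.74 ± 0.43, miR-181a-1-3p by 1.44 ± 0.14 and miR-132-3p by 1.36 ± 0.17. miR-181b-5p fell by 1.43 ± 0.13 on the row of one hairpin and by 1.41 ± 0.13 on that of the other. Adjusted p-values of these miRNAs were 0.0121 or lower. Of all rows, 16.9% had libraries that did not overlap and moved the same way in both environments, where chance gives 1%, and 86 of the 129 were among them. Without Clean_TN replicate 3, miR-31-5p did not pass and 19 of the 20 named miRNAs did. In the shallow libraries alone 35 rows passed and in the deep ones alone 47, with 1 and 2 residual degrees of freedom. Their fold changes correlated across 410 rows (Pearson's r = 0.76, Spearman's rho = 0.73), where miRNAs are not independent replicates.

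Positions are mm10 (GENCODE M21). The hairpin of miR-21a lies in a Vmp1 exon at chromosome 11, 86584067 to 86584158, and that of miR-139 in a Pde2a intron at chromosome 7, 101475376 to 101475443. miR-211 lies in a Trpm1 intron at chromosome 7, 64205806 to 64205911. miR-30a and miR-30c-2 lie near each other on chromosome 1, at 23272269 to 23272339 and 23291701 to 23291784. miR-99b (17830188 to 17830257, a Spaca6 intron) and miR-125a (17830812 to 17830879, a Spaca6 exon) lie side by side on chromosome 17. The miR-181a and miR-181b hairpins form a pair on chromosome 1, at 137966455 to 137966541 and 137966639 to 137966718, and another on chromosome 2, at 38852735 to 38852810 and 38853830 to 38853918. miR-504 lies in an Fgf13 intron at chromosome X, 59097658 to 59097736.

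**Figure D1:**
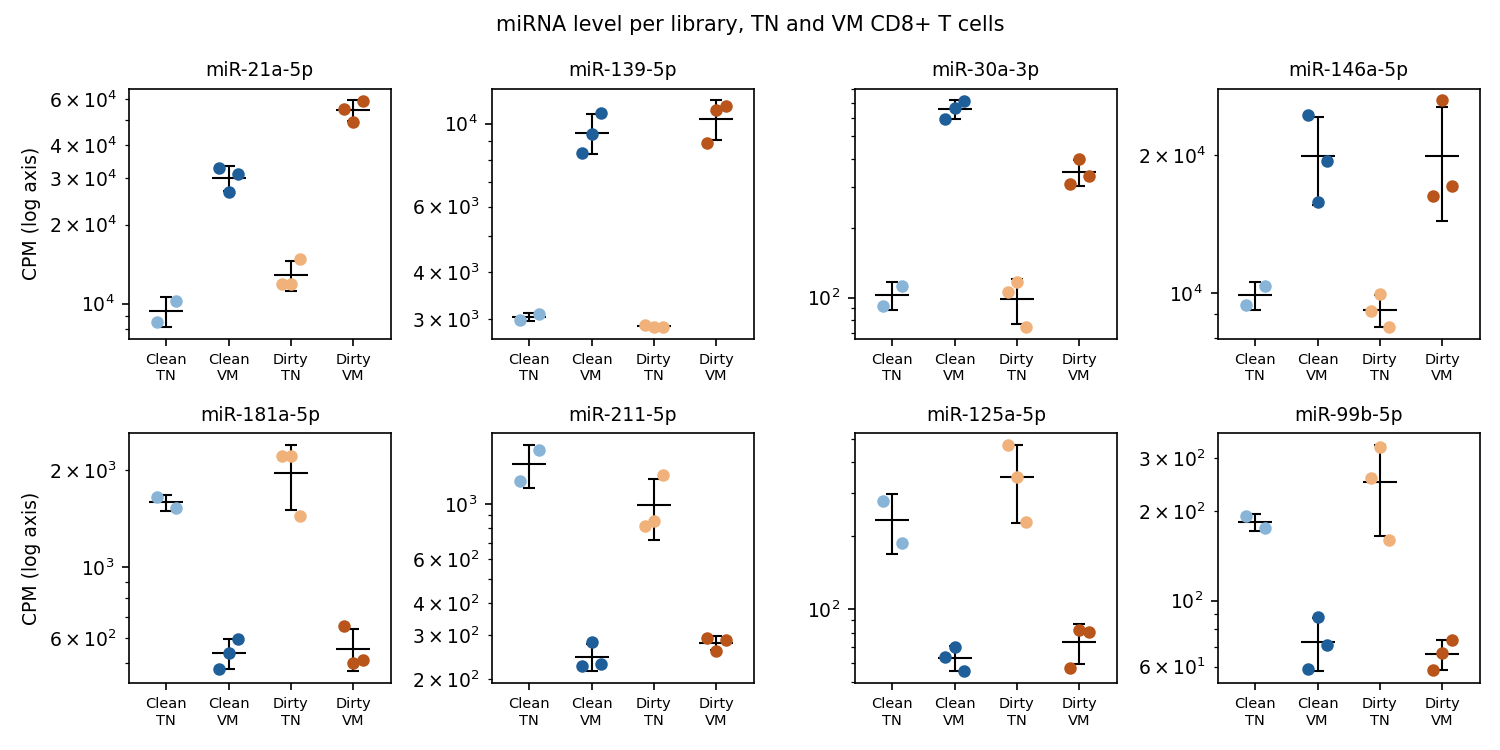
Level in CPM (log axis) of 8 miRNAs in each of the 11 libraries, with the mean and SD per group. miR-21a-5p and miR-139-5p lay higher in every VM library than in every TN library, and miR-181a-5p and miR-211-5p lower.

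T cell activation and memory miRNAs formed one of the fixed lists. Over clean and dirty mice 8 of 13 tested members rose and 2 fell in VM cells, and 10 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.0039, adjusted p = 0.41 with an estimated correlation). Its risers included miR-146a-5p, a feedback inhibitor of NF-kB signalling that targets Traf6 and Irak1, with a log2 change of 1.06 ± 0.16 (adjusted p = 5.6e-04), and miR-222-3p with 0.76 ± 0.13 (adjusted p = 0.0012). miR-155-5p, needed for effector CD8+ T cell responses, rose by 0.6 ± 0.15 (adjusted p = 0.0118). miR-183-5p, miR-96-5p and miR-182-5p, which share 1 cluster, rose by 1.1 ± 0.27, 1.05 ± 0.17 and 0.91 ± 0.23. In dirty mice alone miR-183-5p had a log2 change of 0.02 ± 0.35 and miR-182-5p one of 0.04 ± 0.3, with interactions of -2.17 ± 0.54 (adjusted p = 0.095) and -1.75 ± 0.45 (adjusted p = 0.0952). The members that fell were miR-132-3p and miR-212-5p of the CREB-responsive miR-132/212 cluster, the latter by 1.44 ± 0.47 (adjusted p = 0.041). Without Clean_TN replicate 3, 6 members rose.

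The miR-181 family list was lower, with 2 of 4 members falling, miR-181a-5p and miR-181b-5p (camera adjusted p = 0.0039, adjusted p = 0.484 with an estimated correlation). miR-181c-5p had a log2 change of -0.13 ± 0.19 (adjusted p = 0.671) and miR-181d-5p one of 0.06 ± 0.14 (adjusted p = 0.775), which turned below 0 under scaling to library totals. Of the miR-23/27/24 clusters 4 of 5 members fell, and 5 when adjusted over the list alone (camera adjusted p = 0.00728, adjusted p = 0.499 with an estimated correlation). miR-23a-3p fell by 0.73 ± 0.15 (adjusted p = 0.00304), miR-24-3p by 0.62 ± 0.12 (adjusted p = 0.00286), miR-27a-3p by 0.59 ± 0.12 (adjusted p = 0.00375) and miR-27b-3p by 0.35 ± 0.11 (adjusted p = 0.0401). All 5 lay below 0 under each scaling. In the group of miR-99 and miR-125 2 of 5 members fell, miR-99b-5p and miR-125a-5p, while the list did not pass (camera adjusted p = 0.128). Its median log2 change was 0.45, its mean -0.46, and the test's direction was down.

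The other T cell and family lists did not pass by camera in this comparison. None of 9 let-7 family members passed (camera adjusted p = 0.993). In the miR-17-92 cluster and paralogs 1 of 13 rose and 2 fell (camera adjusted p = 0.502), with miR-92a-3p at 0.42 ± 0.13 and miR-106a-5p at -0.61 ± 0.2. The less abundant row of miR-92a-3p, from the hairpin mir-92a-2, had 0.21 ± 0.15 and did not pass (edgeR adjusted p = 0.331). In the miR-15/16 family 1 of 6 rose, miR-195a-5p by 1.04 ± 0.25 (list 0.79). In the miR-29 family, which targets Tbx21, Eomes and Ifng, miR-29c-3p rose by 0.87 ± 0.23, and all 3 members rose when adjusted over the list alone (list 0.39). In the miR-30 family 1 of 5 rose, miR-30a-5p, and 1 fell, miR-30e-5p by 0.69 ± 0.2 (list 0.889, median -0.31, mean 0.05, direction down). miR-130b-3p, 1 of 2 tested members of the family of miR-130 and miR-301, rose by 0.64 ± 0.17, and that list was too short for a set test. In the family of miR-148 and miR-152 2 of 3 rose, miR-148a-3p by 0.92 ± 0.21 and miR-148b-3p by 0.47 ± 0.15 (list 0.39). In dirty mice alone miR-148a-3p had -0.1 ± 0.28, with an interaction of -2.05 ± 0.43 (adjusted p = 0.0935). Of 8 resting T cell miRNAs miR-139-5p rose and miR-101a-3p fell by 0.74 ± 0.23 (list 0.947). None of 11 Dlk1-Dio3 cluster miRNAs passed (list 0.433). fry, which compares no list with other miRNAs, called the lists of miR-148 and miR-152 (adjusted p = 0.00159), of miR-99 and miR-125 (0.0229) and of miR-29 (0.0496) for movement in 1 direction. For change in either direction it called the resting T cell list (adjusted p = 2.0e-06), the miR-30 (0.00145) and miR-15/16 families (0.0077), the group of miR-99 and miR-125 (0.00722) and the miR-17-92 list (0.0443).

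**Figure D2:**
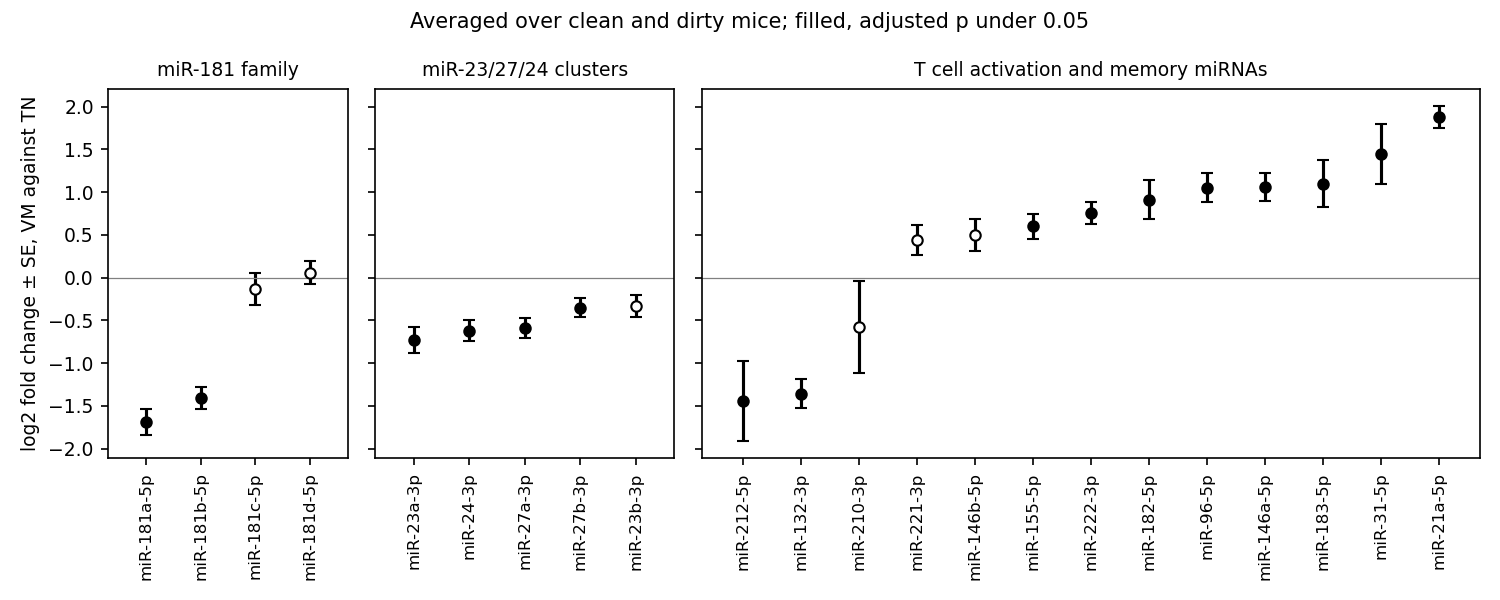
Log2 fold change ± SE of VM against TN cells, averaged over clean and dirty mice, for each tested member of the miR-181 family, the miR-23/27/24 clusters and the activation and memory list. Filled points had an adjusted p under 0.05, which 2, 4 and 10 members reached.

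miRNAs of other cell types were measured in the same libraries. The erythroid miR-451a stood at 15.1, 16.9, 15.5 and 20.2 CPM in Clean_TN, Clean_VM, Dirty_TN and Dirty_VM, with a log2 change of 0.27 ± 0.38 (adjusted p = 0.638). Of 4 tested erythroid miRNAs 2 rose in VM cells, miR-486a-5p by 1.14 ± 0.27 and miR-486b-5p by 1.17 ± 0.25. In clean mice alone their log2 changes were 1.88 and 1.91, and in dirty mice miR-486a-5p had 0.4. Whether the 2 rows count the same reads was not tested, so they may be 1 signal entered as 2 list members. That list did not pass by camera (adjusted p = 0.219), and it passed as higher with the depth class as a term (adjusted p = 0.029) and by fry (adjusted p = 0.0432). The myeloid miR-223-3p, alone tested in its list, stayed between 0.985 and 1.9 CPM and did not pass. The endothelial miR-126a-3p rose by 0.87 ± 0.24 (adjusted p = 0.0208), from 18.2 to 36 CPM in clean and from 22.4 to 37.7 CPM in dirty mice, 1 of 2 tested in its list. Of 7 stromal miRNAs miR-143-3p rose by 0.8 ± 0.18 (list 0.733), of 7 epithelial ones miR-200a-3p rose by 0.72 ± 0.13 and miR-429-3p by 0.51 ± 0.17 (list 0.39 by camera), and of 4 hepatocyte and muscle ones miR-122-5p rose by 0.76 ± 0.26 (list 0.733). By fry the epithelial list was higher in VM cells (adjusted p = 6.4e-04), also in clean (0.00219) and dirty mice (0.0047).

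The question in clean mice alone was which miRNAs separate VM from TN cells in that environment. miR-151-5p, from a Ptk2 intron, was 25.9-fold higher in VM cells, at 374 ± 65.7 CPM (SD, n = 3) against 14.4 ± 0.762 (n = 2), and its partner arm miR-151-3p stood at 1130 ± 223 against 252 ± 39.5. In dirty mice miR-151-5p stood at 46.7 ± 28.1 CPM in VM and 79.1 ± 68.4 in TN cells (log2 change -0.75 ± 0.8, adjusted p = 0.622), its interaction was -5.45 ± 1.31 (adjusted p = 0.102), and its averaged change did not pass (adjusted p = 0.0541). miR-30c-2-3p rose from 10.5 ± 0.0499 to 105 ± 7.31 CPM, miR-139-3p from 100 ± 4.01 to 824 ± 88.2 and miR-30a-3p from 102 ± 14.4 to 655 ± 60.3. miR-148a-3p rose from 633 ± 57.1 to 2450 ± 588 CPM, and miR-183-5p from 69.9 ± 0.914 to 319 ± 17.8. miR-211-5p fell from 1440 ± 286 to 245 ± 31 CPM, miR-181a-5p from 1590 ± 90.8 to 539 ± 57.7 and miR-125a-5p from 233 ± 64.8 to 63.1 ± 7.33.

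In the fit for clean mice 95 rows passed, 53 higher and 42 lower in VM cells. miR-151-5p had a log2 change of 4.7 ± 1.09 (adjusted p = 0.0219), miR-30c-2-3p 3.31 ± 0.37 (adjusted p = 1.1e-04), miR-139-3p 3.04 ± 0.42 (adjusted p = 3.4e-04) and miR-30a-3p 2.68 ± 0.25 (adjusted p = 2.6e-05). miR-211-5p fell by 2.55 ± 0.24 (adjusted p = 2.6e-05), miR-125a-5p by 1.88 ± 0.3 (adjusted p = 9.8e-04) and miR-181a-5p by 1.56 ± 0.22 (adjusted p = 4.6e-04). The other named increases, in miR-183-5p, miR-151-3p, miR-130b-5p, miR-148a-3p, miR-8103 and miR-486b-5p, lay between 1.91 and 2.19. The other named decreases lay between -1.75 and -1.34 and comprised miR-181a-1-3p, miR-181a-2-3p, both rows of miR-181b-5p, miR-339-3p, miR-132-3p and miR-99b-5p. All 95 were rows whose libraries did not overlap, as were 52.7% of all rows, where chance gives 20%. Without Clean_TN replicate 2 34 rows passed, without Clean_TN replicate 3 33, and without Clean_VM replicate 3 61. Leaving out Clean_TN replicate 2 ended the calls of miR-151-5p, miR-130b-5p, miR-8103 and miR-181a-2-3p, so 16 of the 20 named miRNAs passed. Leaving out Clean_TN replicate 3 also left 16, without miR-151-5p, miR-8103, miR-486b-5p and miR-181a-2-3p, and leaving out Clean_VM replicate 1 or 3 ended the call of miR-181a-2-3p (19 of 20). Under library totals alone the median log2 change of all rows moved from 0.082 to -0.127 and the counts to 40 higher and 55 lower. That scaling moved the median from 0.158 to -0.025 for dirty against clean in TN cells, from 0.081 to 0.191 in VM cells, and from -0.045 to 0.236 for the interaction.

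Of the activation and memory miRNAs 8 of 13 rose and 1 fell in clean mice (9 and 1 when adjusted over the list alone, camera adjusted p = 0.0113, adjusted p = 0.524 with an estimated correlation). They included miR-146a-5p with 1.01 ± 0.25 and miR-155-5p with 0.95 ± 0.23, both at an adjusted p of 0.0146. Of the miR-23/27/24 clusters 4 of 5 fell (5 over the list alone, camera adjusted p = 0.00476, adjusted p = 0.535 with an estimated correlation). Of the miR-181 family 2 of 4 fell (camera adjusted p = 0.0334, adjusted p = 0.544 with an estimated correlation), and the other two lay above 0 under TMM scaling and 1 of them below 0 under library totals. With the depth class as a term the miR-181 family list did not pass (adjusted p = 0.0617). Without Clean_TN replicate 2 or 3 only 3 activation and memory miRNAs rose, without Clean_VM replicate 3 4 and without Clean_VM replicate 2 5. In the miR-23/27/24 clusters 1 member fell without Clean_TN replicate 2.

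In dirty mice the same question was asked of Dirty_VM against Dirty_TN. miR-21a-5p had the smallest p, rising from 12900 ± 1640 (SD, n = 3) to 54400 ± 5000 CPM (n = 3) with a log2 change of 2.08 ± 0.17 (adjusted p = 9.4e-06). miR-139-5p rose from 2880 ± 21.5 to 10300 ± 1250 CPM (1.84 ± 0.16, adjusted p = 1.2e-05), and miR-504-5p from 67.3 ± 16.9 to 201 ± 24.6 CPM (1.58 ± 0.21, adjusted p = 2.7e-04). miR-181a-2-3p fell from 77.7 ± 38.7 to 5.44 ± 1.06 CPM, a log2 change of -3.84 ± 0.46 (adjusted p = 1.3e-04). miR-125a-5p fell from 350 ± 123 to 73 ± 13.8 CPM (adjusted p = 1.6e-04), miR-99b-5p from 249 ± 84.6 to 66.2 ± 7.73 CPM (adjusted p = 2.7e-04) and miR-181a-5p from 1960 ± 449 to 556 ± 83.7 CPM (adjusted p = 1.2e-04).

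Among the 545 rows 66 passed in dirty mice, 34 higher and 32 lower in VM cells. The other named increases lay between 1.2 and 2.22 on the log2 scale, in miR-30c-2-3p, miR-30a-3p, miR-1949, miR-139-3p, miR-30a-5p, miR-130b-5p and miR-149-5p. The other named decreases lay between -1.83 and -1.33, in miR-211-5p, miR-467e-3p, miR-466a-3p, both rows of miR-181b-5p and miR-132-3p. All 66 were rows without overlap, as were 30.5% of all rows, where chance gives 10%. Leaving out Dirty_VM replicate 3 left 42 rows and ended the call of miR-467e-3p (19 of 20). Without Dirty_VM replicate 2 miR-139-3p, miR-30a-5p and miR-130b-5p did not pass (17 of 20), and without Dirty_TN replicate 2 or 3 miR-30a-5p did not. Of the miR-181 family 2 of 4 fell (camera adjusted p = 0.00155, adjusted p = 0.378 with an estimated correlation). Of the activation and memory miRNAs 5 rose and 1 fell (5 and 2 over the list alone, camera adjusted p = 0.0227, adjusted p = 0.378 with an estimated correlation), among them miR-146a-5p with 1.12 ± 0.22 and miR-221-3p with 1.09 ± 0.24. That list did not pass with the depth class as a term (adjusted p = 0.0924). Of the miR-23/27/24 clusters 1 of 5 fell, which ended under library totals, where 4 of 5 lay below 0, and without any 1 of Clean_TN replicates 2 and 3, Dirty_TN replicates 2 and 3 and Dirty_VM replicates 1 and 2, each leaving 0 (list 0.206).

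Across the 545 rows the VM against TN fold changes in clean and dirty mice had Pearson's r = 0.46 and Spearman's rho = 0.41, where miRNAs are not independent replicates. Higher calls shared by both environments numbered 20, against 3.3 for independent lists, and lower calls 16, against 2.5. No row was called in opposite directions. Of the 95 clean calls 78 had the same sign in dirty mice, and of the 66 dirty calls 61 had the same sign in clean mice.

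**Figure D3:**
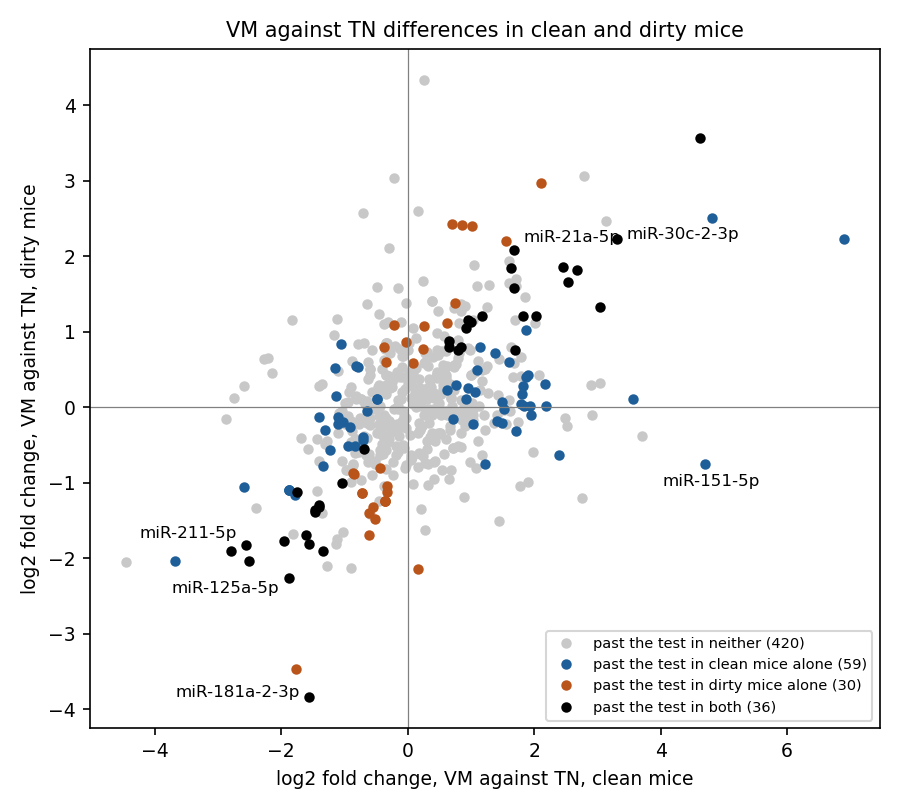
Log2 fold change of VM against TN cells in clean mice (x axis) and in dirty mice (y axis) for the 545 tested rows. Of these 36 passed in both environments, 59 in clean mice alone, 30 in dirty mice alone and 420 in neither.

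Dirty against clean mice was compared within TN cells to ask how the environment changes the miRNAs of naive cells. No miRNA passed (edgeR), with 38 rows at an unadjusted p under 0.05 where 27.2 would be expected by chance, and limma-voom called 0 and DESeq2 3. The smallest p-values belonged to miR-183-5p, at 69.9 ± 0.914 CPM (SD, n = 2) in clean and 234 ± 134 (n = 3) in dirty mice, and miR-182-5p of the same cluster, which represses Foxo1, at 175 ± 6.14 and 463 ± 237. Their log2 changes were 1.74 ± 0.42 and 1.4 ± 0.35, both with an adjusted p of 0.339. miR-5121 had -1.15 ± 0.3 (adjusted p = 0.339), miR-148a-3p 1.1 ± 0.32 and miR-128-3p 0.95 ± 0.32 (adjusted p = 0.559). No let-7 family member passed, and the list was higher in dirty mice as a set (camera adjusted p = 0.0112, adjusted p = 0.692 with an estimated correlation), with all 9 members above 0 under TMM and 7 under library totals. No activation and memory miRNA passed either, 2 were higher when adjusted over the list alone, and the set was higher (camera adjusted p = 0.0237, adjusted p = 0.665 with an estimated correlation). Dirty_TN replicate 3 lay nearer to both Clean_TN libraries than to the other Dirty_TN libraries, with median absolute log2 differences over 263 rows of 0.156 and 0.217 against 0.477 and 0.368. Without it 28 rows passed, including all 5 miRNAs named here. Leaving out the dirty library nearest the clean ones widens the difference and narrows the spread. More calls were therefore to be expected and are no separate support.

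In VM cells the dirty against clean comparison called 0 miRNAs by edgeR, with 81 rows at an unadjusted p under 0.05, while limma-voom called 1 and DESeq2 19. miR-21a-5p stood at 30100 ± 3230 CPM (SD, n = 3) in clean and 54400 ± 5000 (n = 3) in dirty mice, a log2 change of 0.85 ± 0.17 (adjusted p = 0.089). miR-151-3p stood at 1130 ± 223 and 407 ± 105 CPM (-1.48 ± 0.31, adjusted p = 0.089) and miR-30a-3p at 655 ± 60.3 and 349 ± 45.4 (-0.91 ± 0.2, adjusted p = 0.089). miR-361-3p had 0.82 ± 0.18 (adjusted p = 0.089) and miR-186-5p 0.84 ± 0.2 (adjusted p = 0.0932). No list passed by camera, and fry called the activation and memory list for change in either direction (adjusted p = 0.00641). Without Dirty_TN replicate 3, which is in neither group but enters the spread, 26 rows passed, including these 5. Without Clean_VM replicate 1 3 rows passed, without Dirty_TN replicate 1 5 and without Dirty_TN replicate 2 3.

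Averaged over TN and VM cells, dirty against clean mice differed at 0 rows by edgeR, with 28 rows at an unadjusted p under 0.05, and limma-voom and DESeq2 each called 1. The smallest p was that of miR-21a-5p, with a log2 change of 0.66 ± 0.13 (adjusted p = 0.0882), followed by miR-8117 with -1.72 ± 0.46 (adjusted p = 0.631). miR-132-3p (0.59 ± 0.17), miR-8110 (-3.54 ± 1.06, at 0.0813 to 1.21 CPM) and miR-200b-5p (0.61 ± 0.19) had an adjusted p of 0.683. The miR-29 family was lower in dirty mice as a set (camera adjusted p = 0.0135, adjusted p = 0.743 with an estimated correlation) with no member passing and all 3 below 0 under each scaling. The activation and memory list was higher as a set (camera adjusted p = 0.00207, adjusted p = 0.261 with an estimated correlation), with no member passing and 2 when adjusted over the list alone. The shallow libraries alone, with 1 residual degree of freedom, gave 4 calls and the deep ones, with 2, gave 0. Across the 545 rows the dirty against clean fold changes in TN and in VM cells had Pearson's r = 0.21 and Spearman's rho = -0.23.

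The interaction asked whether the VM minus TN difference itself differed between environments. No row passed by edgeR, with 93 rows at an unadjusted p under 0.05, while limma-voom called 0 and DESeq2 41. In the simulated data this contrast called 17.9% of the log2 changes of 1 and 49.5% of those of 2. The absence of calls therefore does not show that the difference was the same in both environments. miR-361-3p, from a Chm intron, had an interaction of 1.32 ± 0.27 on the log2 scale and miR-148a-3p one of -2.05 ± 0.43, both with an adjusted p of 0.0935. miR-1291 had 1.9 ± 0.42 (adjusted p = 0.095), with levels of 38.3, 18.5, 22.6 and 40.7 CPM in Clean_TN, Clean_VM, Dirty_TN and Dirty_VM. The interaction of let-7f-5p was -1.25 ± 0.34 (adjusted p = 0.102), and the let-7 family list did not pass (camera adjusted p = 0.0503, adjusted p = 0.75 with an estimated correlation), though it passed as lower with the depth class as a term (adjusted p = 0.0451). Without Dirty_TN replicate 3 73 rows passed, including the 3 named here, and without Clean_VM replicate 1 1 row passed. Since Dirty_TN replicate 3 lay apart from its group, leaving it out narrows the spread, so its 73 calls are no separate support.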

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

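In this part the tests of a wrong label, of a preparation difference and of depth were chosen after the result was seen, unlike the interaction tests and the counts of splits. For 9 named miRNAs every library moved one way in one subset or environment and the opposite way in the other, and none of their interaction tests passed in edgeR. The environment difference ran opposite ways in TN and VM cells for all of them except miR-186-5p, and the VM minus TN difference ran opposite ways in clean and dirty mice for miR-361-3p, miR-186-5p and miR-1291. Single outlying libraries were not tested within groups of 2 or 3. The interaction on the log2 scale was -2.05 for miR-148a-3p (adjusted p = 0.0935), 1.32 for miR-361-3p (0.0935), 1.63 for miR-5121 (0.095), 1.9 for miR-1291 (0.095) and -1.75 for miR-182-5p (0.0952). It was -0.95 for miR-10a-5p (0.114), 1.0 for miR-186-5p (0.116), 1.27 for miR-339-3p (0.126) and 0.62 for miR-181a-1-3p (0.278).

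Dirty_TN replicate 3 lay nearest the Clean_TN libraries by the median over 263 rows of 10 CPM or more, though not for every miRNA: it had 10.3 CPM of miR-151-5p (79.8 and 147 in Dirty_TN replicates 1 and 2, 14.9 and 13.9 in Clean_TN) but 42.1 of miR-10a-5p (47 and 42.1, 27.9 and 31.9) and 14800 of miR-21a-5p (11900 and 11900, 8500 and 10200). The environment differences of 8 of the miRNAs above ran opposite ways in TN and VM cells. Opposite differences were what flagged them, so their number is no evidence of a general pattern. Across all 545 rows the environment differences in the 2 subsets had r = 0.21 and rho = -0.23. Depth is argued against as the whole cause of the position of Dirty_TN replicate 3. A deep TN library lay 0.477 (median absolute log2 difference) from it and a shallow one 0.217. A single wrong label on that library remains a candidate explanation, which single miRNAs do not decide, since its largest difference from a Clean_TN library, 0.217, was below its smallest from its own group, 0.368. A preparation difference shared by Clean_VM and Dirty_TN replicates 1 and 2 cannot be told apart from an environment response opposite in TN and VM cells. The departure of Dirty_TN replicate 3 from its group correlated positively with the dirty minus clean difference in VM cells, and both would give that sign. Its r was 0.79 across 140 rows with a mean of 100 CPM or more and 0.44 across 263 rows of 10 CPM or more. The other libraries gave -0.63 to 0.39 and -0.61 to 0.33, each against the difference in the subset it did not belong to. Dirty_TN replicates 1 and 2 gave -0.57 and -0.6 across the 140 rows, taken from means that hold replicate 3. These values are therefore no like benchmark for 0.79. A response to the environment, or uneven exposure of the dirty mice, stays open and was not tested.

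VM and TN cells differed at 95 rows in clean mice. A preparation difference shared by Clean_VM and Dirty_TN replicates 1 and 2 would run the other way in dirty mice, and 78 of the 95 had the same direction there, which argues against it as the whole cause. With the depth class as a term 89 of the 95 were called, which argues against depth. Averaged over both environments, 1 of 100 splits of the libraries, the real one, gave as many calls as its 129, and the highest other gave 54. That is the smallest share 100 splits can give, which makes chance unlikely but does not exclude it. The splits also treat the libraries as independent, which the labels do not show. RNA of other cell types was not weighed as a source, and a biological difference between the subsets stays a hypothesis, found and tested on the same data.

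In dirty mice the real split of 6 libraries gave 66 calls and the highest other 13, with 1 of 10 splits as large, too few splits for a share under 0.05. For dirty against clean mice the real split gave 0 calls, which every split equals or exceeds, 10 of 10 in VM cells and 100 of 100 averaged over both subsets, so these counts say nothing about chance. The highest other split called 2 in VM cells and 53 in the average, and so large a count points to a structure of the samples. That split kept both Clean_TN libraries with Dirty_TN replicate 3, as did splits with 23 and 21 calls, while one with 27 calls parted the Clean_TN libraries. Another split with that grouping gave 4 calls, and most of the drawn splits with it gave 0. Keeping these libraries together was therefore not enough to give many calls.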

How the results depend on the processing

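The depth class, by library total, was chosen as an alternative after the totals were seen. The 147 results followed here were the largest changes, the smallest p-values, the list members that passed and some list members that did not. None reversed over 3257 values under the alternatives; outside them, for example, miR-181d-5p (VM against TN averaged) and 2 let-7 family members (dirty against clean in TN cells), which had not passed, turned below 0 under library totals. Of the values 2863 kept direction and side of the threshold, 315 were no longer past it and 79 came past it. Of 118 named results past the threshold 57 stayed past it under every alternative run. Of 194 values of counts, correlations and shares under the alternatives, 145 stayed within their limits, 47 moved and 2 reversed. Unless stated, the cause was not tested. For VM against TN in clean mice the replicate block gave 56 calls and leaving out 1 library 33 to 120, where a group of 1 was assumed to vary like the others. Correlations of departures between TN and VM libraries of the same replicate number ran from -0.46 to 0.42. They were above 0 where both libraries shared a depth class and below 0 where they did not. They therefore cannot show whether the libraries were paired. In dirty mice leaving out 1 library gave 42 to 94, and averaged over environments 86 to 145. Fewer libraries were fitted in the shallow class, which gave 35 calls, and in the deep class, which gave 47. For dirty against clean in TN cells DESeq2 gave 3, no filter 4 and leaving out 1 library 0 to 28. In VM cells DESeq2 gave 19, limma-voom 1, library totals 2, no filter 16, the stricter filter 2, the compared groups alone 18, and leaving out 1 library 0 to 26. Averaged over subsets DESeq2, limma-voom and no filter each gave 1, the shallow class 4, and leaving out 1 library 0 to 0. For the interaction DESeq2 gave 41, no filter 30, the stricter filter 16 and leaving out 1 library 0 to 73. The correlation of dirty against clean fold changes between TN and VM cells reversed from 0.21 to -0.1 under the stricter filter, which tests fewer miRNAs. The share of the 20 most abundant miRNAs was 0.23 points higher in VM cells, the reverse of the 10 most abundant.

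With an estimated correlation 0 lists passed in each of the comparisons in which camera called any. fry called 5 lists by direction and 6 in either direction for VM against TN in clean mice, 4 and 6 in dirty mice, and 8 and 9 averaged. For dirty against clean fry called 0 and 0 in TN cells, 1 in either direction in VM cells, and 0 and 1 averaged. With the depth class as a term 2 lists passed in clean mice, without the miR-181 family (adjusted p = 0.0617), and 1 in dirty mice, without the activation and memory list (0.0924). In that fit 4 passed averaged over environments, with the erythroid list added (0.029), and 1 for the interaction, the let-7 family (0.0451). Depth limits miRNAs near 1 CPM: 3 counts were 1.157 CPM in the shallowest library and 0.186 CPM in the deepest.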

Other observations

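The clusters and arms described here were chosen after the data were seen, as were the tests of the pattern weighed below. miRNAs of a large Sfmbt2 intron, a rodent cluster of near-identical hairpins, were lower in VM cells, averaged over clean and dirty mice (edgeR). Of 45 tested rows in its 2 segments 24 passed as lower and 41 lay below 0, with a median log2 change of -0.72. Some rows hold identical counts under different names: counted once, 39 rows remained, of which 19 passed as lower and 35 lay below 0, with a median of -0.68. The set tests take such rows as separate members. The first segment, at mm10 chromosome 2, 10466663 to 10489202, held 27 rows, 14 of them lower (camera adjusted p = 1.7e-05 over 14 clusters, adjusted p = 0.148 with an estimated correlation). The second, at 10505721 to 10518279, held 18 rows, 10 of them lower (camera adjusted p = 6.5e-04, adjusted p = 0.148 with an estimated correlation). miR-467c-3p fell by 1.15 ± 0.27 (SE, adjusted p = 0.00699). On chromosome X the mir-450b to mir-322 cluster, at 53047997 to 53054349, had 5 of 9 rows lower with a median of -1.47 (camera adjusted p = 0.00117, adjusted p = 0.148 with an estimated correlation). The mir-99b to mir-125a cluster, at chromosome 17, 17830188 to 17830879, had 3 of 5 rows lower with a median of -1.62 (camera adjusted p = 6.3e-04, adjusted p = 0.148 with an estimated correlation). In the mir-429 to mir-200b cluster on chromosome 4, at 156053905 to 156055750, 4 of 5 rows were higher with a median of 0.67 (camera adjusted p = 0.0456, adjusted p = 0.148 with an estimated correlation).

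Both arms of 137 hairpins were tested, and their VM against TN log2 changes, averaged over environments, correlated across hairpins (Pearson's r = 0.61, Spearman's rho = 0.52). Where either arm passed, 50 of 57 hairpins had arms with the same sign. Where both passed, 18 of 18 hairpins had arms with the same sign. miR-21a rose by 1.88 on the 5p and 1.56 on the 3p arm (adjusted p = 0.00686), and miR-195a by 1.04 and 2.09. miR-211 fell by 2.19 and 1.87 (adjusted p = 0.00132), and miR-132 by 1.65 and 1.36. miR-204-5p, whose seed is that of miR-211-5p, fell by 2.28 (adjusted p = 0.0012), while its 3p arm had 1.25 (adjusted p = 0.323). Its log2 changes in clean and dirty mice, -2.51 and -2.04, were near those of miR-211-5p, -2.55 and -1.83. Whether the 2 rows share reads was not tested, so the fall of miR-204-5p may not be a separate one. miR-142a-5p fell by 0.9 (adjusted p = 0.0128) with its 3p arm at -0.14.

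For the lower level of the Sfmbt2 intron miRNAs in VM cells, depth is argued against, since 24 of the 24 lower calls, with repeated rows counted, were also made with the depth class as a term. Reads shared between near-identical copies stay open: the 7 miRNAs with mostly whole counts had a mean log2 change of -0.49 (SE 0.18), but their median level was 4.34 CPM, too low to decide. A biological difference between the subsets stays open as well and was not tested.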
